A study of Homo sapiens with 4 samples.

How the data were processed

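Total RNA was sequenced from 4 libraries of human peripheral blood mononuclear cells, 2 given vehicle (0.1% DMSO) and 2 given 500 nM ganetespib for 24 hours. The labels' treatment field put each library in its group, and the replicate number is the number in its title. The labels' protocols name a column kit for RNA extraction and the sequencing company's standard library preparation, and do not say whether ribosomal RNA was depleted, poly(A) RNA was selected or strand was kept. Genes that overlap others on the opposite strand may therefore share reads.

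The authors deposited 1 table of raw counts per gene for the whole series, with 56808 rows and 4 columns, although its header calls the values reads per kilobase. All values (100%) are whole numbers, the column totals differ, and of 958 nonzero values in genes of 80 to 150 bases 66.8% equal 1, 2 or 3, which values per kilobase could not take. The median of the mean count rose from 46.2 in the shortest protein-coding genes to 1034.5 in the longest. At mean counts of 5 to 40 the chi-square per gene between the vehicle replicates was 2.51 for short genes and 2.52 for long genes, and between the ganetespib replicates it was 2.03 and 1.85. The unit was settled from these values. Per the submitters' processing notes, CASAVA, DESeq2 and the genome build mm10 were used, with no role or order given. That build is of the mouse while the gene names and the cells are human. The aligner, the counter, the annotation and the treatment of reads that match several genes are not given in the sources used here. For that reason no coordinates are printed.

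Of the rows, 576 name no gene and hold 0.063% of the counts, and these stayed out of library sizes and tests. A further 1748 rows carry a name that occurs more than once (0.17% of the counts). They were kept as separate features, and a list member with several rows was read from the row with the highest mean. XIST, TSIX and Y-linked genes were left out before testing because the cells come from people. This left 55796 features. Gene length, GC content and gene type came from GENCODE release 29, with older symbols matched through RefSeq synonyms: 35644 rows matched (62.7%), holding 98.6% of the counts.

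The design written before the data were examined assumed length-normalised values and a log-scale limma test, and named edgeR as the test to use if the file held raw counts. The count test was therefore the one used. edgeR 4.0.16 in R 4.3.3 filtered genes with filterByExpr, computed TMM factors (1.04, 0.989, 0.993 and 0.979 in the order vehicle 1, vehicle 2, ganetespib 1, ganetespib 2) and fitted the 4 libraries with glmQLFit and glmQLFTest, with the group as the only term. Tests were two-sided, with Benjamini-Hochberg adjustment over the 17874 genes tested and a threshold of 0.05. The common biological coefficient of variation was 0.0948. Standard errors of log2 fold changes are the fold change divided by the square root of the F statistic. Levels are counts scaled to a common library total (CPM) with the TMM factors, as mean ± SD over the 2 libraries of a group. The totals were 29910223 and 33516907 (vehicle) and 24299389 and 27755590 (ganetespib), so that 3 counts correspond to 0.09 to 0.123 CPM. That value served as the floor for genes without counts in a group, summed over the group. For 1 to 3 counts the ratio has an exact 95% counting interval. Replicates differed by more than sampling noise. The chi-square per gene was 16.6 in the vehicle pair over 18194 genes and 8.30 in the ganetespib pair over 16924 genes. Each library was therefore counted as its own sample. This spread does not show whether the libraries came from separate donors, separate cultures or repeated preparations.

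Gene lists, 31 in number and holding 686 genes of which 9 stand in more than 1 list, were fixed before the data were examined. They cover chaperones, stress pathways, interferon and inflammation, antigen presentation, checkpoint molecules, markers of the blood cell types, growth and metabolism. Each was tested with camera in limma 3.58.1 with a preset correlation of 0.01, Benjamini-Hochberg adjusted over the 31 lists. With an estimated correlation 0 lists passed after adjustment and 6 had an unadjusted p under 0.05. That version takes its degrees of freedom from the 4 libraries, so a list can rarely pass it here. B cell markers (estimated correlation −0.03) and HSP90 cochaperones (−0.01) lay below the preset correlation and still failed, both at an adjusted p = 0.23. For these lists, failing it therefore does not show that correlation between genes made the call. Other called lists had estimated correlations far above the preset. They were 0.96 for the aryl hydrocarbon receptor list, 0.51 for monocyte markers, 0.45 for class II and 0.27 for heat shock. The p-values that camera gave such lists with the preset correlation may be far too small. Fry passed 15. The rule for naming genes, also fixed then, took the 12 largest rises and 12 largest falls past the threshold with both treated values on the same side of both vehicle values, up to 4 passing members per list with the largest change (or the 2 most abundant where none passed), and HSP90AA1, HSP90AB1, HSPA1A, HSPA1B, DNAJB1, HSPA8, CD274, IFIT1, HLA-DRA, CD14 and CD3E. Small RNAs, pseudogenes, names without a symbol and antigen receptor segments were excluded from the largest changes. Some genes that the rule takes are not reported here. Any gene outside the rule is said to be named after its value was seen.

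Alternatives planned beforehand were a replicate block, no filter, a mean of at least 5 CPM, median-ratio scaling, a 2-fold minimum (glmTreat), DESeq2 1.42.0 without filterByExpr, limma on log2(CPM + pseudocount) with 0.5 or 0.1, with quantile normalization, without trend and with array weights, and leaving out each library in turn. The pseudocount and the mean-value filter had been planned for length-normalised values and were applied to CPM. Limma with a pseudocount of 1, upper-quartile scaling and library totals alone were added after seeing the data. With 1 library left out, the lone library of its group is assumed to vary like the other group.

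The edgeR, limma and DESeq2 tests and camera with the preset correlation were tried on simulated counts with the real genes' means and library sizes and 200 changed genes. Fry, glmTreat and camera with an estimated correlation were not. Among the 17874 genes of this comparison, edgeR recovered 44% of genes changed 1.5-fold, 54% of those changed 2-fold, 86% of those changed 4-fold and 86% of those changed 8-fold, with 1.46% false calls. Limma recovered 44, 56, 86 and 86% (2.86% false calls), and DESeq2 40, 54, 78 and 82% (2.31%). Camera found the 1 shifted list and 0 of 30 unshifted lists. Simulated genes were drawn independently, while real lists had estimated correlations such as 0.45 (class II) and 0.51 (monocyte markers). The simulation therefore does not measure false calls of correlated lists. Its 200 changed genes are also far fewer than the 5837 called in the data, so its recovery rates may not carry over. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.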

Results

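The study measured gene expression in human peripheral blood mononuclear cells (PBMCs), the lymphocytes, monocytes and dendritic cells that a density gradient separates from blood. The cells were kept overnight in medium with plasma of the same donor and then received, for 24 hours, either the solvent (DMSO at 0.1%) or ganetespib at 500 nM. Ganetespib occupies the ATP pocket of HSP90, a chaperone that keeps many kinases, receptors and transcription factors folded. Total RNA was sequenced from 2 vehicle and 2 ganetespib libraries, and the comparison asked how exposure to the inhibitor changes gene expression in immune cells. Gene counts summed to 29910223 and 33516907 in the vehicle libraries and to 24299389 and 27755590 in the ganetespib libraries. Mitochondrially encoded genes took 1.81 and 1.44% of the counts in the vehicle libraries and 1.55 and 2.06% in the ganetespib libraries. Across the tested genes, which are not independent replicates, the correlation of log2(CPM + 1), where CPM is the count scaled to a common library total, was 0.995 within the vehicle pair, 0.997 within the ganetespib pair and 0.975 to 0.981 between groups. The labels do not say whether the libraries of a group came from separate donors or separate cultures, so the p-values measure the spread between these samples, which may be technical.

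Chaperone genes rose together with ganetespib. HSP90AA1, the inducible cytosolic HSP90, went from 1347 ± 146 to 5425 ± 214 CPM (mean ± SD, n = 2 per group), a 4.03-fold rise. HSPH1, an HSP110 chaperone, rose 4.67-fold, and HSPA1B, an inducible HSP70, rose 5.74-fold from 17.5 ± 3.03 to 101 ± 17.6 CPM. Of 27 tested targets of HSF1, the transcription factor that HSP90 holds inactive, 21 rose, 1 fell and 5 were not past the threshold, with a median log2 fold change of 1.12. Adjusted over the list alone, 22 rose and 1 fell. HSPA4L rose by 3.99 ± 0.39 on the log2 scale (± standard error, as for every log2 value here) and RGS2, a G protein signalling regulator, by 3.22 ± 0.10. HSPA1A (1.82 ± 0.13), DNAJB1 (1.70 ± 0.10) and HSPA8 (1.08 ± 0.11) rose less. The member that fell was HSPA6, an HSP70 gene, at −1.12 ± 0.18, which was named after its value was seen. HSPA1A and HSPA1B encode nearly identical transcripts, and how reads were divided between them is not given in the sources used here. In edgeR's quasi-likelihood test, the Benjamini-Hochberg adjusted p was 1.6e-09 for HSP90AA1 and 5.7e-10 for HSPA1B. The list differed from the other tested genes by camera (adjusted p = 6.7e-36 with a preset correlation, adjusted p = 0.23 with an estimated correlation).

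HSP90 itself and its cochaperones rose as well. Among 17 members, 11 rose, 2 fell and 4 were not past the threshold, with the same counts adjusted over the list alone and a median of 0.49. AHSA1, which stimulates the HSP90 ATPase, rose by 1.89 ± 0.11, HSP90AB1, the constitutive cytosolic form, by 1.45 ± 0.11, and STIP1, which links HSP70 to HSP90, by 1.27 ± 0.10. The members that fell, named after their values were seen, were FKBP5, a glucocorticoid-regulated cochaperone, at −1.0 ± 0.10, and HSP90B1, the HSP90 of the endoplasmic reticulum, at −0.63 ± 0.11. Camera gave an adjusted p = 1.3e-07 for this list (adjusted p = 0.23 with an estimated correlation).

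**Figure D1:**
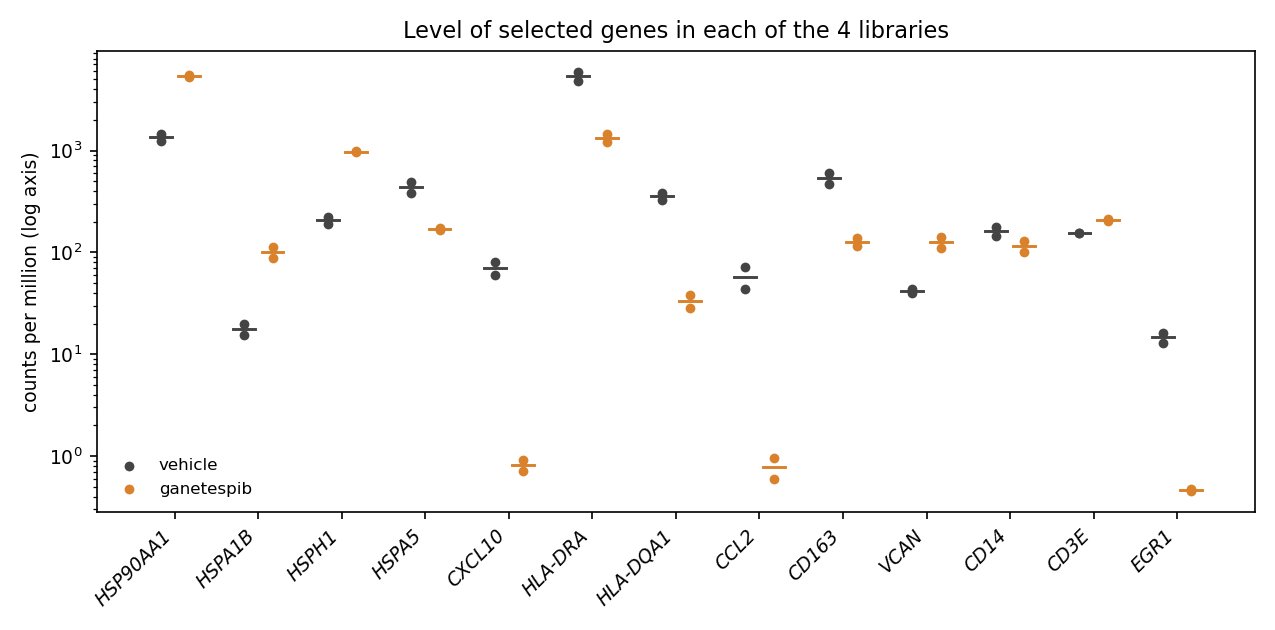
Level in CPM (log axis) of 13 genes in each library, with points for the 2 vehicle and 2 ganetespib libraries and a bar at each group mean. HSP90AA1, HSPA1B, HSPH1, VCAN and CD3E were higher in both ganetespib libraries than in both vehicle libraries, and the other genes drawn were lower in both.

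Over all genes, 5837 of 17874 tested genes changed (32.7%): 2559 rose and 3278 fell at a Benjamini-Hochberg adjusted p under 0.05 in edgeR's quasi-likelihood test. Of these, 404 rose and 1276 fell at least 2-fold, and a test against a 2-fold minimum called 125 higher and 435 lower. The balance of rises and falls depended on the scaling and the libraries: 43.8% of the changed genes were higher here, 38.5% with library totals, 47.1% with median-ratio scaling, 52.1% in limma with quantile normalization (2953 higher, 2717 lower) and 50.5% without vehicle replicate 2 (3086 higher, 3021 lower). The number of genes passing with 1 library left out depended on which pair was left to give the spread. The vehicle pair varied more (chi-square per gene 16.6) than the ganetespib pair (8.3). Lower counts without a treated library therefore do not show that the calls rested on it. Among the 12 largest rises, KL (klotho) rose by 5.06 ± 0.29, KCNE1L, a potassium channel subunit, by 5.05 ± 0.28, and MET, the receptor for hepatocyte growth factor, by 4.87 ± 0.25. EREG, which encodes the EGF receptor ligand epiregulin, went from 2.33 ± 0.0848 to 66.7 ± 12.3 CPM, a 28.7-fold rise, and EMR3, an adhesion G protein-coupled receptor of myeloid cells, rose 16.1-fold. VNN3 (4.03 ± 0.32), HSPA4L (3.99 ± 0.39) and VMO1 (3.80 ± 0.31) rose as well. SYT4 and IL1RL2 had no vehicle counts and were at least 11.7-fold and 10-fold higher, taking a floor of 3 counts over the group (95% counting limits, which also cover the treated counts, 8.89 and 7.54). GCOM1, whose locus shares sequence with its neighbours, and OLFML1 had 2 and 3 vehicle counts, with ratios of 17.5 (95% counting interval 4.42 to 152) and 14.2 (4.46 to 72.2). The fitted value of GCOM1, 3.95 with all libraries, was 6.95 without vehicle replicate 1 and 3.03 without vehicle replicate 2.

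The 12 largest falls held chemokines and EGR transcription factors. CXCL10, an interferon-induced chemokine for T cells, fell from 69.9 ± 13.9 to 0.814 ± 0.152 CPM (84.9-fold lower), and CCL2, which attracts monocytes, fell from 57.9 ± 20.7 to 0.772 ± 0.259 (75.5-fold lower). EGR2 (−5.71 ± 0.17), EGR3 (−5.49 ± 0.24) and EGR1 (−4.95 ± 0.26) fell on the log2 scale. ANKRD22 fell by 5.50 ± 0.29 (−6.27 without ganetespib replicate 2), and F13A1, the coagulation factor XIII A chain, by 5.03 ± 0.15. CCL7 kept 1 count and CXCL11 kept 3 in the treated libraries, with ratios of 0.0102 (95% counting interval 0.000256 to 0.0578) and 0.0303 (0.00616 to 0.0906). Fitted log2 values of CCL7 moved from −6.32 to −5.38 without ganetespib replicate 2, −8.86 without ganetespib replicate 1 and −5.71 without vehicle replicate 2. TMEM26, IL3 and P2RY12 had no treated counts and were at least 19.7-fold, 9.32-fold and 6.12-fold lower against the floor of 3 counts over the group. Their ratios had upper 95% counting limits of 0.064, 0.139 and 0.218. P2RY12 lost its call without ganetespib replicate 1 (adjusted p = 0.064) and without ganetespib replicate 2 (adjusted p = 0.066) in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Counting intervals and floors cover counting error only.

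**Figure D2:**
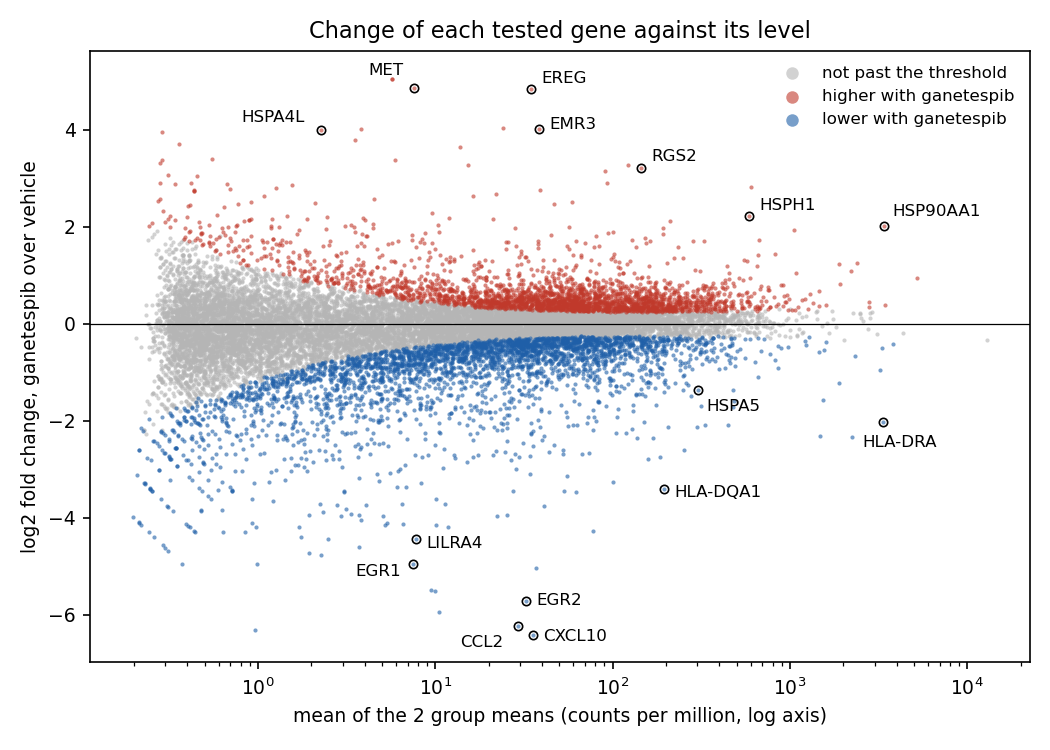
Log2 fold change of ganetespib over vehicle for 17866 tested genes against the mean of the group means in CPM (log axis), with genes past an adjusted p of 0.05 in red (higher) or blue (lower). The 8 tested genes with no counts in a group are not drawn, and circles mark 15 of the genes named in the text, from CXCL10 at −6.41 to MET at 4.87.

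Interferon-stimulated genes fell. Among 38 tested members, 27 fell, 1 rose and 10 were not past the threshold, with a median of −0.75, and adjusted over the list alone 27 fell and 2 rose. CXCL9, a chemokine induced by interferon gamma, fell 6.27-fold from 42.5 ± 11.7 to 6.74 ± 1.83 CPM, and IFI44L fell by 2.58 ± 0.18. IFIT1, an RNA-binding antiviral effector, fell by 0.88 ± 0.21. Some classical members did not follow: MX1 was at 0.03 ± 0.09, and HERC5, the member that rose, was at 0.30 ± 0.11 and had no call without ganetespib replicate 1 or 2, without the filter, with library totals, in DESeq2 or in limma without trend, which leaves 0 members higher. Without vehicle replicate 1, 2 members rose. MX1 and HERC5 were named after their values were seen. Of 29 monocyte markers 22 fell in the same comparison (median −1.30). Camera gave an adjusted p = 1.3e-17 (adjusted p = 0.23 with an estimated correlation).

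Inflammatory mediators split into a group that fell and a smaller group that rose. Of 33 tested cytokines, chemokines and NF-kB targets, 16 fell, 8 rose and 9 were not past the threshold, with a median of −0.30 and 17 lower and 8 higher adjusted over the list alone. CCL2 fell by 6.24 ± 0.27, CCL8, another monocyte chemokine, by 3.95 ± 0.37 and IL1A by 3.85 ± 0.66 (−4.69 without ganetespib replicate 2). TNF (−2.24 ± 0.17) and IL1B (−2.99 ± 0.24) fell too, whereas the neutrophil chemokines CXCL5 (3.39 ± 0.35), CXCL3 (2.22 ± 0.44), CXCL2 (2.14 ± 0.26) and IL8 (1.65 ± 0.13) rose. These 6 genes were named after their values were seen, and CXCL2 and CXCL3 have near-identical sequences that reads may not separate. Monocyte markers (median −1.30) and dendritic cell markers (median −1.26) fell beside this list. It passed camera (adjusted p = 2.5e-03, adjusted p = 0.54 with an estimated correlation) but not fry, which asks whether its genes move on balance in a common direction (adjusted p = 0.11), nor camera with a pseudocount of 0.1 in limma (adjusted p = 0.081).

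Antigen presentation genes fell, with a larger median fall for class II than for class I. Of 15 class II genes, 13 fell, none rose and 2 were not past the threshold, with a median of −2.03 (4.07-fold lower) and 14 lower adjusted over the list alone. HLA-DRA, the alpha chain of HLA-DR, went from 5405 ± 761 to 1328 ± 158 CPM. HLA-DQB1 fell 13.5-fold, HLA-DOA 10.9-fold, HLA-DQA1 10.6-fold and HLA-DOB, at −2.61 ± 0.34, 6.13-fold. CIITA, the master activator of class II transcription, fell by 1.35 ± 0.10 and the invariant chain CD74 by 1.57 ± 0.11, both named after their values were seen. Of 18 class I genes, 13 fell, none rose and 5 were not past the threshold, with a median of −0.56 and 15 lower adjusted over the list alone. The peptide transporter genes TAP1 (−1.16 ± 0.09) and TAP2 (−0.84 ± 0.10), the immunoproteasome subunit PSMB9 (−1.13 ± 0.11) and the chaperone CALR (−1.10 ± 0.11) fell, while HLA-B was at −0.19 ± 0.11 and not past the threshold, named after its value was seen. Camera gave adjusted p = 7.5e-42 for class II and 3.9e-08 for class I (adjusted p = 0.23 and adjusted p = 0.25 with an estimated correlation). Markers of 3 cell types that carry class II molecules fell as well, with medians of −1.30 for monocytes, −1.26 for dendritic cells and −0.62 for B cells. HLA genes are polymorphic and share sequence with each other, and TAP2 stands under a repeated name in the table, so their levels are uncertain.

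Monocyte and dendritic cell markers moved with these groups. Of 29 tested monocyte and macrophage markers, 22 fell, 3 rose and 4 were not past the threshold, with a median of −1.30 (2.46-fold lower) and 23 lower and 3 higher adjusted over the list alone. In limma the median was −0.78 with a pseudocount of 1 and −0.81 with quantile normalization. CCR2, the receptor for CCL2, fell 8.80-fold to 11.3 ± 1.17 CPM, and the complement gene C1QC fell 6.46-fold. FCGR1A, an Fc receptor with near-identical copies, fell by 3.28 ± 0.57 (−4.31 without ganetespib replicate 2), and the scavenger receptor MARCO by 2.79 ± 0.81. MARCO lost its call without ganetespib replicate 1 (−1.90, adjusted p = 0.25) and was at −7.05 without ganetespib replicate 2. CD14, the classical monocyte marker, fell only from 160 ± 24.2 to 115 ± 19.3 CPM (−0.48 ± 0.12), and lost its call without ganetespib replicate 1 (−0.31, adjusted p = 0.21). The 3 markers that rose, named after their values were seen, were the proteoglycan VCAN (1.60 ± 0.12), the Fc receptor FCGR2A (0.74 ± 0.12) and the G-CSF receptor CSF3R (0.50 ± 0.11). Without vehicle replicate 2, 5 markers rose. Of 18 dendritic cell markers, 17 fell, none rose and 1 was not past the threshold, the same counts adjusted over the list alone, with a median of −1.26. The median was −0.56 over the 10 markers with a mean of at least 5 CPM (9 lower) and −0.64 under quantile normalization (13 lower). LILRA4 (21.7-fold lower) and CLEC4C (8.58-fold lower) mark plasmacytoid dendritic cells and CD1E (13.2-fold lower) conventional ones. CCL19 kept 2 treated counts, a ratio of 0.0736 (95% counting interval 0.00857 to 0.287). It lost its call without ganetespib replicate 2 (−2.60 in place of −3.61, adjusted p = 0.15), and was at −7.01 without ganetespib replicate 1. Camera gave adjusted p = 2.9e-21 for the monocyte list and 1.5e-11 for the dendritic cell list (adjusted p = 0.30 and adjusted p = 0.25 with an estimated correlation).

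**Figure D3:**
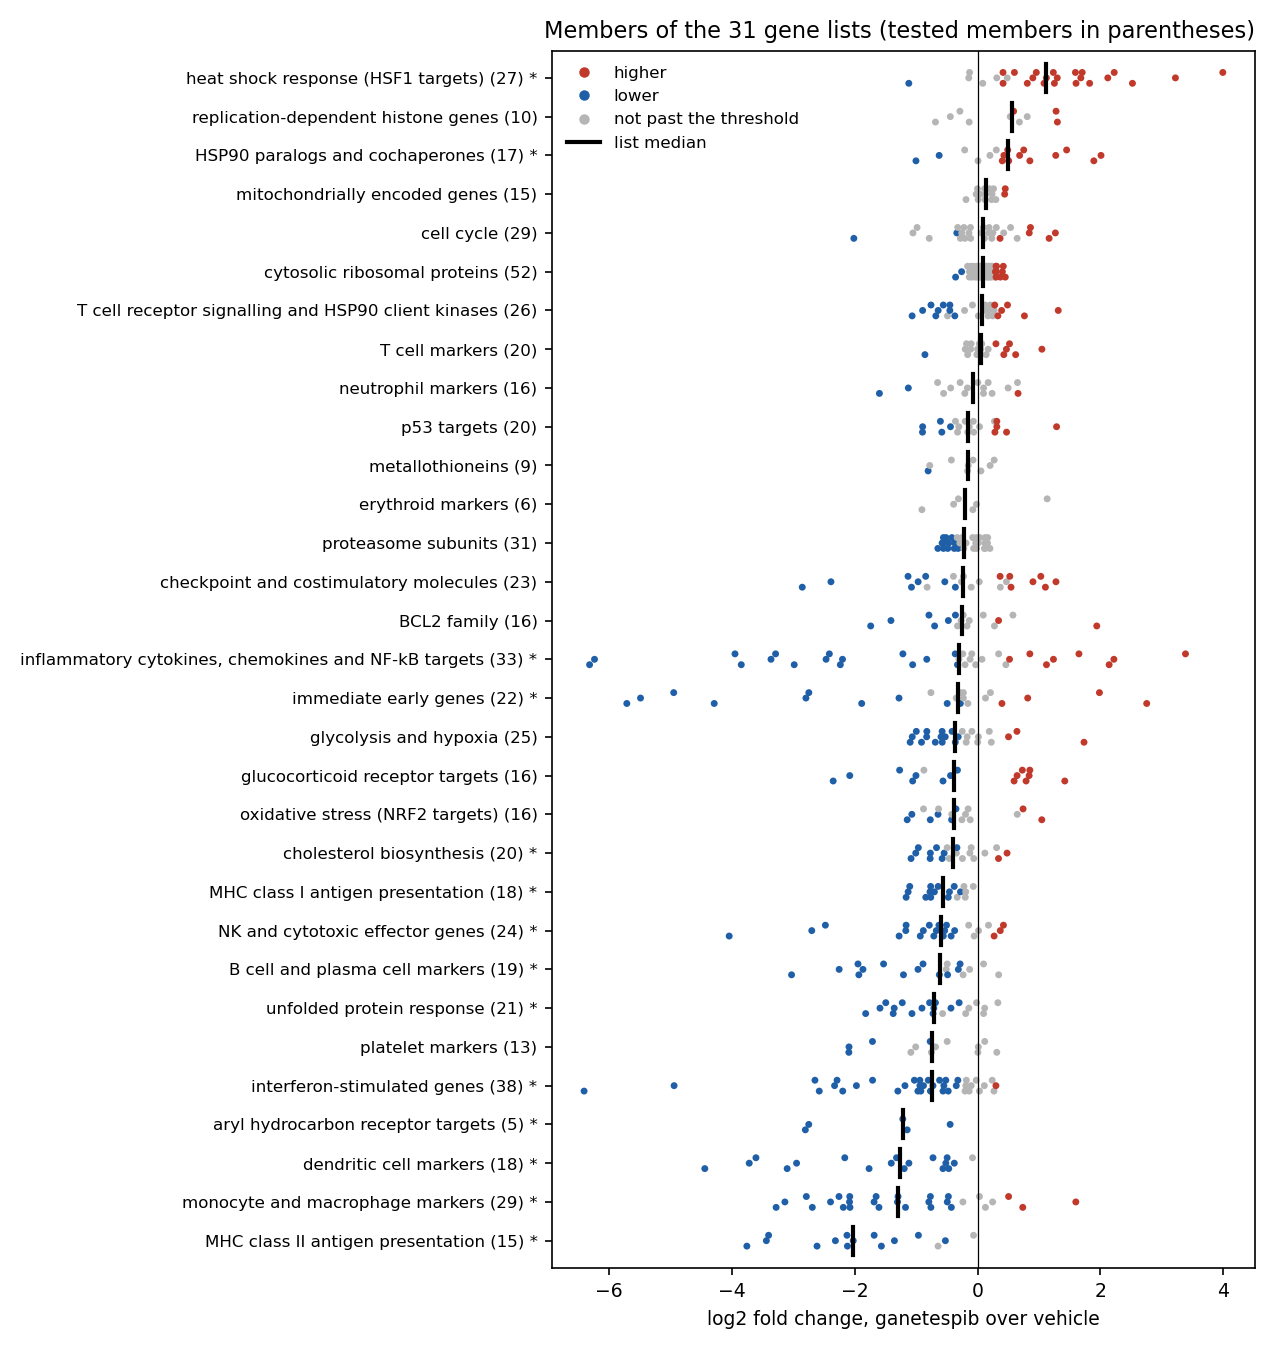
Log2 fold change of ganetespib over vehicle for each tested member of the 31 gene lists, with members past an adjusted p of 0.05 in red (higher) or blue (lower), the list median as a black bar and a star where camera with a preset correlation passed 0.05. The heat shock list has the highest median (1.12) and the MHC class II list the lowest (−2.03).

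B cell and cytotoxic lymphocyte genes fell, while most T cell markers were not past the threshold. Of 19 B cell and plasma cell markers, 13 fell, none rose and 6 were not past the threshold, with the same counts adjusted over the list alone and a median of −0.62. TNFRSF17, the plasma cell receptor BCMA, fell 8.17-fold, the immunoglobulin J chain IGJ 4.77-fold, FCRL1 3.86-fold and the transcription factor SPIB 3.82-fold. Of 24 natural killer and cytotoxic genes, 17 fell, 3 rose and 4 were not past the threshold, the same counts adjusted over the list alone, with a median of −0.59. IFNG, which encodes interferon gamma, went from 7.16 ± 0.307 to 0.431 ± 0.0365 CPM (16.5-fold lower), and the chemokines XCL1 (6.50-fold) and XCL2 (5.57-fold), a near-identical pair, and the receptor KLRC1 (2.43-fold) fell. XCL2 was at −3.23 without ganetespib replicate 2 in place of −2.48. The 3 that rose, named after their values were seen, were CST7, GNLY and PRF1 (0.42, 0.37 and 0.27), and none, 1 and 1 of the list rose without ganetespib replicate 1, ganetespib replicate 2 and vehicle replicate 2. Camera gave adjusted p = 2.3e-08 for the B cell list and 1.6e-07 for the cytotoxic list (adjusted p = 0.23 and adjusted p = 0.41 with an estimated correlation).

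Of 20 T cell markers, 6 rose, 1 fell and 13 were not past the threshold, with the same counts adjusted over the list alone and a median of 0.05. The list did not pass camera (adjusted p = 0.14) but passed fry upward (adjusted p = 0.031). CD5 rose 2.07-fold, CD6 by 0.62 ± 0.11, CD247 by 0.52 ± 0.10 and CD3E from 156 ± 1.32 to 209 ± 7.61 CPM, while the adhesion receptor CD2 fell 1.81-fold. CD3E lost its call without ganetespib replicate 1 (0.39, adjusted p = 0.079), and 2 markers fell without vehicle replicate 1. Checkpoint and costimulatory genes went both ways, with 8 lower, 7 higher and 8 not past the threshold of 23 (median −0.23), the same counts adjusted over the list alone and a camera adjusted p = 0.29. Without ganetespib replicate 1 only 5 of them fell. TNFRSF9, the activation receptor 4-1BB, fell 7.24-fold, CD276 5.23-fold and CD40 2.19-fold. CD274, which encodes PD-L1, fell from 42.8 ± 5.33 to 29.6 ± 0.954 CPM, and CTLA4, an inhibitory receptor of T cells, rose 2.42-fold. T cell receptor and HSP90 client kinase genes were also mixed (6 higher, 9 lower, 11 not past, median 0.07 with a camera direction downward and a mean of −0.07, camera adjusted p = 0.93), and adjusted over the list alone 8 rose and 9 fell. FYN rose by 1.31 ± 0.10, while SRC fell by 1.07 ± 0.13 and LYN by 0.90 ± 0.12. Of these kinase genes 3 rose without ganetespib replicate 1.

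Genes of the unfolded protein response, which senses misfolding in the endoplasmic reticulum, went the opposite way to the cytosolic chaperones. Of 21 tested members, 14 fell, none rose and 7 were not past the threshold, with a median of −0.71, and adjusted over the list alone 15 fell and 1 rose. ATF3 fell by 1.82 ± 0.16, SDF2L1 by 1.59 ± 0.23, MANF 2.82-fold and CRELD2 by 1.37 ± 0.15. HSPA5, the main chaperone of the endoplasmic reticulum (BiP), went from 435 ± 71.8 to 170 ± 4.47 CPM and was named after its value was seen. B cell and plasma cell markers fell too (13 of 19, median −0.62). Camera gave an adjusted p = 7.7e-09 (adjusted p = 0.29 with an estimated correlation).

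All 5 tested genes of the list for the aryl hydrocarbon receptor, a ligand-activated transcription factor, fell, also adjusted over the list alone. Their median was −1.22 (−2.0 over the 4 with a mean of at least 5 CPM). Besides targets, the list holds the receptor gene AHR itself, and NQO1 also stands among the NRF2 targets below. AHRR, the receptor's repressor, fell 6.99-fold and CYP1B1, a cytochrome P450, 6.72-fold. AHR fell 2.33-fold and the quinone reductase NQO1 2.21-fold. Camera gave this list an adjusted p = 1.0e-10 (adjusted p = 0.29 with an estimated correlation of 0.96). Of 22 immediate early genes, 10 fell, 4 rose and 8 were not past the threshold, with a median of −0.32 and 12 lower and 4 higher adjusted over the list alone. The EGR genes fell furthest, and FOSL1 kept 2 treated counts, a ratio of 0.0464 (95% counting interval 0.00548 to 0.176). NR4A2 (2.75 ± 0.12) and FOSL2 (1.98 ± 0.10), named after their values were seen, rose. Of 29 monocyte markers 22 fell beside both lists (median −1.30). Camera gave an adjusted p = 1.5e-04 for the immediate early genes (adjusted p = 0.24 with an estimated correlation). Of 20 cholesterol synthesis genes, 9 fell, 2 rose and 9 were not past the threshold (median −0.40), and adjusted over the list alone 11 fell and 3 rose. The epoxidase SQLE (−1.08 ± 0.11), the sterol sensor INSIG1 (−1.01 ± 0.12), PMVK (−0.97 ± 0.19) and MSMO1 (−0.77 ± 0.10) fell (camera adjusted p = 6.9e-03, adjusted p = 0.45 with an estimated correlation). The genes that rose, MVD and SC5D, were named after their values were seen, and numbered 1, 0 and 1 without vehicle replicate 1, ganetespib replicate 1 and ganetespib replicate 2.

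Several stress and death lists held genes moving apart without a shift of the list by camera. Glucocorticoid receptor targets had 7 higher, 8 lower and 1 not past (median −0.38, camera adjusted p = 0.46, 7 higher and 9 lower adjusted over the list alone), with PER1 2.68-fold higher and CD163 and SGK1 4.23- and 2.41-fold lower. BCL2 family genes had 2 higher, 6 lower and 8 not past (median −0.25, camera adjusted p = 0.21, 3 higher and 7 lower adjusted over the list alone). The death activator HRK rose by 1.94 ± 0.35, and the survival genes BCL2A1 and BCL2L1 fell by 1.41 ± 0.14 and 0.79 ± 0.12. BOK fell by 1.74 ± 0.46 but lost its call without ganetespib replicate 2 (−1.42, adjusted p = 0.088), and 1 BCL2 family gene rose without either ganetespib library. NRF2 targets had 2 higher and 6 lower of 16 (the same adjusted over the list alone, median −0.39, camera adjusted p = 0.28), with FTH1, the ferritin heavy chain, 2.06-fold higher and NQO1, ME1 and PRDX1 2.21-, 2.10- and 1.71-fold lower. Without vehicle replicate 1, 10 NRF2 targets fell and camera gave an adjusted p = 0.012. Of 9 tested metallothionein and zinc genes only SLC30A1, a zinc exporter, fell, by 0.81 ± 0.13, also adjusted over the list alone (median −0.15, camera adjusted p = 0.59), but 7 fell without vehicle replicate 1 (camera adjusted p = 0.014), 4 rose without vehicle replicate 2 and 1 rose without ganetespib replicate 2. Of 20 p53 targets, 5 rose and 5 fell (6 and 5 adjusted over the list alone, median −0.15, camera adjusted p = 0.90), with GADD45A 2.44-fold higher and CDKN1A, TP53I3 and FAS 1.86-, 1.86- and 1.52-fold lower. TP53I3 lost its call without ganetespib replicate 1 (−0.80, adjusted p = 0.058), and 2 p53 targets rose without either ganetespib library.

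Among housekeeping and growth lists, 14 of 25 glycolysis and hypoxia genes fell and 3 rose (median −0.36, 15 and 3 adjusted over the list alone), PFKFB3, a glycolytic regulator, by 1.73 ± 0.11, while DDIT4 (−1.06 ± 0.22) and PFKFB4 (−1.0 ± 0.15) fell. ADM fell by 1.10 ± 0.34 but was not past the threshold without ganetespib replicate 1 (−1.18, adjusted p = 0.073) or ganetespib replicate 2 (−1.01, adjusted p = 0.13). Camera gave this list an adjusted p = 0.14, and 0.012 without vehicle replicate 1, and 9 members fell without either ganetespib library. Of 31 proteasome subunits 12 fell, among them PSMD14 (−0.65 ± 0.11), PSMA5 (−0.58 ± 0.11), PSMA4 (−0.56 ± 0.11) and PSMA3 (−0.56 ± 0.10), and none rose (14 lower adjusted over the list alone, median −0.22, camera adjusted p = 0.11). Without vehicle replicate 1 camera gave the proteasome an adjusted p = 0.012, without ganetespib replicate 1 only 6 subunits fell, and without vehicle replicate 2, 2 rose. Cell cycle genes had 5 higher, 2 lower and 22 not past (the same adjusted over the list alone, median 0.09, camera adjusted p = 0.36), with the replication genes MCM6 2.24-fold higher and CDC6 4.04-fold lower. TK1 (1.27 ± 0.38) and E2F1 (0.86 ± 0.29) lost their calls without ganetespib replicate 1 (1.13, adjusted p = 0.12, and 0.66, adjusted p = 0.27) and without vehicle replicate 2 (1.0, adjusted p = 0.055, and 0.73, adjusted p = 0.061). The cell cycle counts became 2 higher and 1 lower without ganetespib replicate 1, while 4 were lower without vehicle replicate 1 and 1 without ganetespib replicate 2.

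Of 52 cytosolic ribosomal protein genes, 9 rose, 2 fell and 41 were not past the threshold (6 and 0 adjusted over the list alone), with a median of 0.08 and a camera direction that turned downward under quantile normalization. RPS19 (0.45 ± 0.12), RPL19 (0.42 ± 0.12) and RPS3 (0.40 ± 0.10) rose, but without ganetespib replicate 1 none of the list rose and these stood at 0.28, 0.26 and 0.35 with adjusted p of 0.29, 0.34 and 0.18. Without vehicle replicate 2, 20 ribosomal genes rose, and without ganetespib replicate 2, 5 did. None fell without vehicle replicate 2 or ganetespib replicate 2, and 1 fell without ganetespib replicate 1. Camera gave an adjusted p = 0.058, which was 0.012 without vehicle replicate 2 and 0.014 without ganetespib replicate 2. Of 15 mitochondrially encoded genes, MT-ND1 and MT-RNR2 rose by 0.45 ± 0.14 and 0.44 ± 0.13 (the same 2 adjusted over the list alone, median 0.13, camera adjusted p = 0.21). Without ganetespib replicate 2 neither was past the threshold (0.22 and 0.26, adjusted p = 0.43 and 0.38), and without vehicle replicate 1, 10 rose. Camera then gave the mitochondrial list an adjusted p = 0.011, and 2.6e-04 without ganetespib replicate 1. Of 10 tested histone genes, HIST1H2AC (1.30 ± 0.15), HIST2H2BE (1.28 ± 0.20) and HIST1H2BK (0.59 ± 0.14) rose, also adjusted over the list alone (median 0.56, and 1.26 over the 3 with a mean of at least 5 CPM). Camera gave the histones an adjusted p = 0.066.

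Markers of neutrophils, platelets and red cells were tested as well. Of 16 neutrophil markers, 2 fell, 1 rose and 13 were not past the threshold, the same adjusted over the list alone (median −0.08, camera adjusted p = 0.59, with a direction that turned upward under quantile normalization). MMP9, which monocytes also make, fell 3.03-fold, the chemokine receptor CXCR1 fell 2.19-fold, and CRISP3 rose by 0.66 ± 0.19 but lost its call without ganetespib replicate 1 (0.64, adjusted p = 0.064), which left 0 higher. Without vehicle replicate 1, 2 neutrophil markers rose. Of 13 platelet markers, ITGA2B (−2.10 ± 0.34), TREML1 (−2.09 ± 0.53), NRGN (−1.71 ± 0.35) and GP1BA (−0.77 ± 0.21) fell and none rose, the same adjusted over the list alone (median −0.75, camera adjusted p = 0.17). The platelet median was −0.30 without ganetespib replicate 1, −1.32 without ganetespib replicate 2 and −0.21 with quantile normalization. TREML1 lost its call without ganetespib replicate 1 (−1.70, adjusted p = 0.091) and was at −2.68 without ganetespib replicate 2, and GP1BA lost its call without vehicle replicate 2 (−0.51, adjusted p = 0.084). None of 6 tested erythroid genes passed, over all genes or adjusted over the list alone, with HBB at −0.02 ± 0.13 and EPB42 at −0.08 ± 0.16, and both turned positive under quantile normalization. The erythroid median was −0.20 and the mean −0.10, while camera's direction was upward (adjusted p = 0.98). At an unadjusted p under 0.05, 1 of the 6 passed in edgeR (HBA2 at 1.13, named after its value was seen and sharing reads with its copy HBA1), and after adjustment DESeq2 and limma with a pseudocount of 1 called 0.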

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

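No gene called both in the results above and under an alternative changed sign. The count of changed genes (5837) ran from 4450 with DESeq2 to 7196 with the replicate block, apart from the left-out libraries below and the 2-fold minimum, which left 560 (125 higher, 435 lower) and 11 of 21 raised heat shock genes, since it asks for more. Leaving out each library gave 1346 to 3086 genes higher, 2065 to 3586 lower and 3411 to 6453 changed, and the heat shock median stayed between 1.09 and 1.22. Same-numbered libraries deviated together only weakly (r = 0.117 across genes, 0.0529 with a pseudocount of 0.1) and there are 2 pairs, so the numbers are not read as pairs. The higher count with the replicate block (7196 against 5837) may reflect pairing, which stays open. The replicate block raised list calls from 14 to 17 and ended none. With an estimated correlation, which a list can rarely pass with 4 libraries, 0 lists passed. The inflammatory list also failed with fry (adjusted p = 0.11) and with camera in limma at a pseudocount of 0.1 (0.081). Glycolysis, the proteasome, ribosomal proteins, histones and T cell markers (the last with fry) gained a call under some settings. NRF2 targets, metallothioneins and mitochondrial genes gained a call only with 1 library left out. The cause was not tested. Of 138 genes the naming rule took, quantile normalization ended 8 calls, limma without trend 6, DESeq2 2, library totals 1 and limma with a pseudocount of 1 ended 1, all with the sign kept, and the cause was not tested. Leaving out ganetespib replicate 1 ended 14, ganetespib replicate 2 6 and vehicle replicate 2 3, with fewer samples. Directions turned only for lists and genes without a call in the results above. Among these, ribosomal proteins, NRF2 targets, metallothioneins and mitochondrial genes had a call under another setting. Camera's direction turned for neutrophil markers (median 0.10) and ribosomal proteins (0.02) under quantile normalization, the kinase list at a pseudocount of 0.1 (0.07) and erythroid markers with fry (−0.20), the replicate block (−0.19) and a pseudocount of 0.1 (−0.18). Leaving out 1 library turned it at least once for NRF2 targets (medians −0.57 to −0.11), metallothioneins (−0.47 to 0.32), kinases (0.04 to 0.07), erythroid markers (−0.53 to 0.04), p53 targets (−0.22 to 0.01) and mitochondrial genes (−0.13 to 0.34). HBB turned to 0.01 with median-ratio scaling and DESeq2, 0.07 with quantile normalization, and EPB42 to 0.07 with the latter. Without 1 library they ran from −0.11 to 0.11 and from −0.16 to 0.04. With 2 libraries per group the simulation recovered 54% of 2-fold changes.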

Other observations

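Tests of the 10 further gene lists were chosen after the main fold changes had been seen (for the ERK, CREB and secretory lists before the results of these lists were looked at), and the test of fewer monocytes after its own values had been seen. Several families of immune receptors had more members lower than higher. Of 29 monocyte markers, 22 fell beside them and beside the oxidase and complement genes below (median −1.30). Of 13 tested chemokine receptors, 7 fell and 2 rose (median −0.90), with CCR1 at −3.26 ± 0.15 against CCR4, a receptor of helper T cells, at 1.14 ± 0.10. That list lacks CXCR4, which rose by 1.19 ± 0.10 and stands in the CREB list below. Of 11 leukocyte immunoglobulin-like receptor family genes, 9 fell and none rose (median −1.01), LILRA1 by 2.75 ± 0.21 on the log2 scale and LILRB1 by 1.37 ± 0.12. Of 12 Siglec genes, which encode sialic acid receptors, 7 fell and none rose (median −1.25), SIGLEC1 by 2.61 ± 0.20. Members of these families share sequence, so reads may not be fully separated between them. Of 14 Toll-like receptor and adaptor genes, 9 fell and none rose (median −0.61), with TLR7 at −1.88 ± 0.16 and MYD88 at −0.75 ± 0.11.

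In the phagocyte oxidase, CYBB, the catalytic subunit mutated in chronic granulomatous disease, fell by 1.22 ± 0.15, NCF4 by 1.21 ± 0.12 and NCF1, which has near-identical pseudogenes, by 1.90 ± 0.23 (4 of 6 genes lower). Of 14 complement genes, 10 fell and 2 rose (median −0.76), with SERPING1, the C1 inhibitor, at −2.04 ± 0.16 and the membrane regulators CD46 (0.35 ± 0.09) and CD59 (0.31 ± 0.12) higher. Of 8 subunit genes of the cytosolic chaperonin TRiC, which folds actin and tubulin, 5 were higher and none lower (median 0.36). The other 3 were not past the threshold. TCP1 was at 0.97 ± 0.10 and CCT3 at 0.87 ± 0.09. Camera gave an adjusted p = 6.2e-04 (adjusted p = 0.36 with an estimated correlation of 0.81). The TRiC list was chosen with the fold changes already seen, so its p-values are not an independent test.

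The fall of monocyte markers (median −1.30 over 29 genes, −0.81 with quantile normalization in limma) may reflect fewer monocytes, lower marker expression per cell, or a bias. If only monocytes expressed these markers, fewer monocytes as the only cause would lower every marker alike. Instead 3 members (VCAN, FCGR2A and CSF3R) lay above 0 by more than 3 standard errors. By the same measure 13 lay above the list median. Expression of the markers in other cells was not measured, so these values do not exclude fewer monocytes as the only cause. With a smooth trend of fold change on gene length and GC content removed over 15337 genes, the median was −1.14, which argues against such a trend as the whole cause. A partial loss of monocytes together with regulation of the genes stays open, because cell numbers were not measured in these data.

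Endoplasmic reticulum stress genes fell (median −0.71) while cytosolic chaperones rose. Scaling was compared: under library totals, median-ratio and upper-quartile scaling the median closest to 0 was −0.69. The fall therefore did not depend on the choice among these. They differ little, with a median over all tested genes of −0.075 with library totals and −0.009 with median-ratio scaling. The comparison could thus hardly have come out otherwise and does not exclude a scaling bias that they share. Loss of cells rich in secretory machinery, such as plasma cells, cannot be told apart from regulation. Of 28 constitutive translocon, signal recognition and glycosylation genes, 13 fell, 3 rose and 12 were not past the threshold. Their median was −0.26 (95% bootstrap interval −0.40 to 0.02 over 2000 draws), less than the fall of the stress genes. The bound set in advance lay inside the interval. These genes had an estimated correlation of 0.43 and each group holds 2 libraries, so the interval may be too narrow. A lower load on the endoplasmic reticulum or a direct effect of the inhibitor on its sensors was not tested.

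A hypothesis from the fall of EGR1, EGR2, EGR3 and FOS is that signalling through the kinase ERK was lower after 24 hours. Of 13 tested ERK feedback and target genes not looked up before, 7 fell and 3 rose, with a median of −1.10. Camera in limma gave an adjusted p = 0.0061 over the 10 further lists, which is consistent with lower ERK signalling. ETV5 (−2.94 ± 0.37), DUSP6 (−2.46 ± 0.17) and HBEGF (−2.22 ± 0.23) fell, DUSP4 (0.71 ± 0.19) rose, and the list did not pass fry (adjusted p = 0.11) or camera with an estimated correlation (adjusted p = 0.41). Monocyte markers (22 of 29 lower, median −1.30) and dendritic cell markers (median −1.26) fell in the same comparison, and a change of cell types was not tested for this list and stays open.

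The rise of NR4A2, CREM, PER1 and RGS2, which cAMP induces through CREB, led to a further hypothesis of higher cAMP and CREB signalling. EGR1 (−4.95 ± 0.26) and FOS, immediate early genes like NR4A2, fell and were not counted against this hypothesis. In the immediate early list 10 genes fell and 4 rose, and NR4A2 was picked from those that rose. Of 12 tested CREB target genes not looked up before, 10 rose and 2 fell, with a median of 0.97. Camera gave an adjusted p = 1.7e-09 (adjusted p = 0.21 with an estimated correlation). These rises go with the hypothesis, within a list that leaves out EGR1 and FOS. The phosphodiesterase genes PDE4D (1.71 ± 0.09) and PDE4B (1.29 ± 0.10) and the kinase SIK1 (1.10 ± 0.10) rose, while PER2 (−0.68 ± 0.14) and THBD (−1.04 ± 0.28) fell. The test shows the expression of target genes, not cAMP levels or CREB activity, and RGS2 is also in the heat shock list. Monocyte markers (22 of 29 lower, median −1.30) and dendritic cell markers (median −1.26) fell in the same comparison. B cell and cytotoxic medians were −0.62 and −0.59, and that of T cell markers was 0.05 (6 of 20 higher, 1 lower). None of these medians reached the 0.97 of the CREB list, but T cell markers passed fry upward (adjusted p = 0.031). Cell numbers were not measured, and expression of the markers per cell may have changed. A change of cell types was not tested for this list and stays open.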
